A study of Mus musculus with 16 samples.

How the data were processed

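Glomeruli had been isolated from 1 kidney per mouse by iron perfusion and a magnet, and libraries were made with the Illumina TruSeq mRNA Sample Prep kit, per the labels' protocols. These name the tissue of origin as kidney, and the extraction text describes RNA from the isolated glomeruli. All 16 mice had the same genotype, and the labels give 9 as untreated and 7 as given the RAAS-blocking drugs. Each library is taken to be a separate mouse from the treatment protocol; the labels do not say so sample by sample, and the p-values measure the spread between these libraries.

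The deposited table holds FPKM values made by the authors, fragments normalized for transcript length and for the fragments mapped in the library, with 1 column per library and 25791 gene symbols in rows. The submitters' processing notes name CASAVA 1.8.2, FastQC, TopHat2 2.0.8, Cufflinks and Cuffdiff 2.2.1, with no roles or order. The genome build, the annotation and whether strand was used are not given in the sources used here, so no coordinates are printed, and reads from overlapping or antisense genes cannot be told apart. The table holds 4177 symbols listed at 0 in every library. Of 841 symbols of the fixed lists found in the table, 5 are among them (Ccl21a, Ccl28, Cyp11b1, Hmgcs1 and Podxl). Podxl is a podocyte gene and its neighbours in the podocyte list are abundant, so a 0 here can be a failed estimate, and symbols are only said to be listed at 0. FPKM depends on which other transcripts are counted, so a very abundant RNA in some libraries lowers the values of the rest. Mir27a was listed at 672307 FPKM in untreated replicate 7, at 743781 FPKM in RAAS_blocked replicate 5 and at 0 elsewhere, and short RNAs like this did not pass the filter.

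Absolute depth is unknown, because the table has no counts. The low values moved in steps, so relative depth could be estimated from genes with very low values. Against untreated replicate 0, a median of 90 such genes gave 75.2% to 91.8% of ratios at the commonest step, its double or its halving (within 0.05 on the log2 scale), and 15 libraries lay between 1 and 1.69 times the depth of untreated replicate 0. For RAAS_blocked replicate 4 only 40% of 30 ratios fell on a step and no depth is given; it had 16919 symbols above 0, the fewest of all, against 17993 to 18613 in the others. No pair of libraries was identical, and pairwise Pearson correlations over tested genes ran from 0.89 to 0.98.

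Values were tested as log2(FPKM + 1) with R 4.3.3 and limma 3.58.1. Genes with at least 1 FPKM in at least 7 libraries were kept (13286). The model had group as its only term, the variance was moderated with a mean trend and robust settings, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. A fold change on this scale understates the change of low genes. Before the data were examined, 43 gene lists were fixed, of lipid pathways, the renin-angiotensin-aldosterone system, kidney responses and cell type markers, and the 40 with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over lists. The mitochondrially encoded, adrenal and urothelial lists had fewer and were left out. The same lists were tested with an estimated correlation, with fry, and by exact two-sided permutation of list scores over all 11440 splits of the libraries. Coordination of the 6 lipid lists is the mean pairwise correlation of their genes within a group, compared by exact two-sided permutation of group-centred values.

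The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 genes with the greatest rise and up to 12 with the greatest fall among those past the threshold with a group mean of at least 2 FPKM, leaving out predicted and unnamed symbols and small RNAs. It also takes up to 4 members of each list with the lowest p, and Ren1, Ace, Agtr1a, Nos3, Lepr, Scd1, Scd2, Dgat1, Dgat2, Plin2 and Cd36 in any case. In use this part of the rule was narrowed by a cut that depends on the list tests. For lists that passed, for the lipid lists and for the RAAS components up to 4 members were taken, and 1 for the rest. Lists that passed therefore have more named genes. Some genes that the rule takes are not reported here, which leaves 97. Genes named outside the rule are said to have been chosen after their values were seen, except markers given to describe the libraries.

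Alternatives covered the pseudocount, the filter, scaling, quantile normalization, array weights, the variance model, a replicate block, a rank test and leaving out each library. A covariate for sex was planned only if both sexes were present and was not run. The functions were tested on simulated data with the real means and spreads of the 13286 genes and 200 genes changed. In this comparison of 9 with 7 libraries, 64.2% of the 67 genes changed by 0.5 on the log2 scale were recovered, 80.3% of the 67 changed by 1 and 95.5% of the 66 changed by 2, and 8.6% of the calls were genes left unchanged. The simulation had no correlation between genes, so it does not carry the shared variation of tubule content. The p-value that passes the adjustment also depends on how many genes change. With 200 genes changed it was less strict than in the real data, so these shares are not the power of the real comparison.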

Results

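Glomerular RNA was sequenced from 16 mice that were homozygous for the db mutation of the leptin receptor gene and lacked endothelial nitric oxide synthase. This cross combines obesity and type 2 diabetes with endothelial dysfunction and is used as a model of diabetic kidney disease. In 7 of the mice the renin-angiotensin-aldosterone system (RAAS) was blocked with lisinopril, an inhibitor of angiotensin-converting enzyme, at 20 mg/day. They also received losartan, an antagonist of the angiotensin II type 1 receptor, at 30 mg/day. Both drugs were given in drinking water from 10 to 12 weeks of age until 26 weeks. The other 9 mice were untreated. The title of the series names triacylglycerol metabolism in the diabetic kidney as its subject. The comparison reported here is RAAS-blocked against untreated mice of this genotype. Mice without diabetes were not analysed here. Expression is given as FPKM, with 1 value per gene and library, and fold changes are differences of log2(FPKM + 1), RAAS-blocked minus untreated, ± SE.

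The genes altered in the model and the makeup of the preparations were read first. Nos3, which encodes endothelial nitric oxide synthase, was at 25.0 ± 10.6 FPKM (SD, n = 9) in untreated and 24.0 ± 6.54 FPKM (n = 7) in RAAS-blocked libraries. A value for the whole gene does not show whether a targeted allele is functional. Lepr was at 0.379 ± 0.0929 FPKM in untreated and 0.588 ± 0.429 FPKM in RAAS-blocked libraries, below the level needed for testing. Xist did not exceed 0.114 FPKM and the Y-linked Eif2s3y did not fall below 23.2 FPKM in any of the 16 libraries, so all carried the male pattern. Podocyte genes were abundant throughout, with Nphs1 (nephrin) between 181 and 470 FPKM. Podxl, another podocyte gene, was listed at 0 in every library, as was Hmgcs1 of the cholesterol pathway, and neither could be compared.

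Tubule content varied far more between mice than between groups. Slc34a1, the phosphate transporter of the proximal tubule, ranged from 2.59 to 241 FPKM, a 93.3-fold range, and Umod (uromodulin), made in the thick ascending limb, from 107 to 1168 FPKM. The mean level of the convoluted proximal tubule markers followed the first principal component, which held 33.7% of the variance, with a Pearson r of 0.83 (permutation p = 5.0e-05, two-sided, 16 libraries) and a Spearman rho of 0.80 (permutation p = 0.00035). The r was 0.71 without the 2 libraries farthest from the median level, 0.85 within the untreated group and 0.79 within the RAAS-blocked group. Neither the proximal tubule level (exact permutation p = 0.799) nor the podocyte level (exact permutation p = 0.526) differed between the groups beyond the spread between mice.

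**Figure D1:**
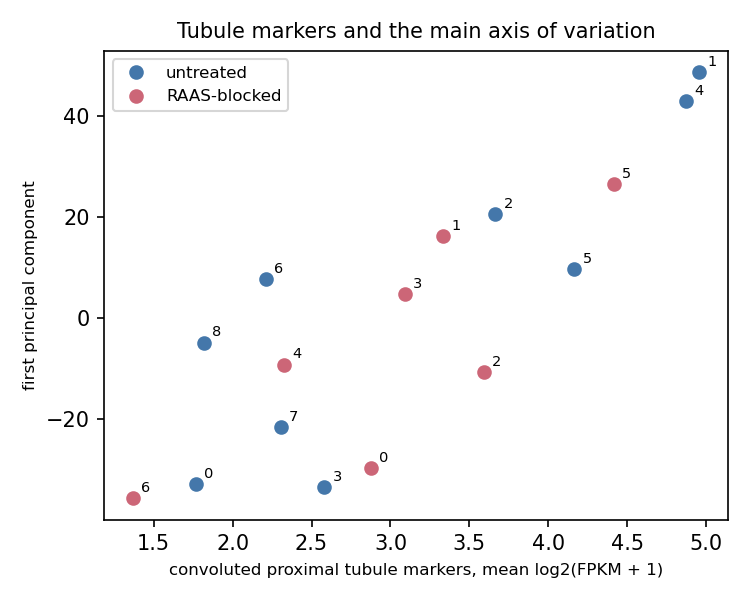
Each point is a library, numbered by replicate and coloured by group; the x axis gives the mean log2(FPKM + 1) of the convoluted proximal tubule markers and the y axis the first principal component of all tested genes. Libraries of both groups spread along both axes, with r = 0.83 over the 16 libraries.

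The comparison of RAAS-blocked with untreated glomeruli yielded few changes in single genes. Mgat1, which encodes the enzyme that starts the synthesis of hybrid and complex N-glycans, fell from 60.2 ± 2.90 FPKM (SD, n = 9) to 48.1 ± 2.70 FPKM (SD, n = 7). Its log2 fold change was -0.32 ± 0.05 with a limma adjusted p of 0.044, and all 7 treated libraries lay below the lowest untreated one. Rn18s, the symbol for 18S ribosomal RNA, was listed at 0 in all 9 untreated libraries and at 2214 to 9925 FPKM in all 7 treated ones (limma adjusted p = 3.5e-15), and no fold is given against a group at 0. Among 25791 symbols it was the only one at 0 in every library of 1 group and above 1 FPKM in every library of the other. Of 13286 genes tested, these were the only genes past an adjusted p of 0.05, 1 higher and 1 lower. At the same time 814 genes had an unadjusted p under 0.05 (664 would by chance), 360 of them higher and 454 lower. An exact Wilcoxon test per gene had 757 at an unadjusted p under 0.05 and called 0, as the design makes likely: the lowest p it can give here, 0.00017, passes only if 47 genes reach it, and 8 did. In limma Mgat1 passed in 4 of the 16 fits that left out 1 library each. The Mgat1 call also depended on Rn18s being among the genes tested, since its adjusted p was 0.088 without Rn18s, and on the scaling (0.135 with upper-quartile scaling and 0.174 with quantile normalization). The library identifiers in the labels formed 2 unbroken runs, 1 for each group, and 0 runs held both groups, so anything done run by run coincided with treatment.

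Ren1, which encodes renin and is released from feedback when angiotensin signalling is blocked, had a mean of 64.7 ± 76.1 FPKM in untreated and 982 ± 579 FPKM in RAAS-blocked libraries, a 15.2-fold ratio. Untreated replicate 3 was at 263 FPKM, and without it the untreated mean was 39.9 FPKM and the ratio 24.6-fold. The log2 fold change over all libraries was 3.85 ± 0.76 with a limma adjusted p of 0.218, so the difference did not pass the test over all genes. In 6 of 7 treated libraries Ren1 lay between 443 and 1584 FPKM, above every untreated library, while RAAS_blocked replicate 4 was at 33.5 FPKM. Akr1b7, an aldo-keto reductase made by renin cells, went with it, at 7.33 ± 4.09 FPKM untreated and 21.3 ± 9.50 FPKM treated (log2 1.32 ± 0.40, limma adjusted p = 0.613), with RAAS_blocked replicate 4 at 2.70 FPKM. Without that replicate Ren1 (log2 4.56, limma adjusted p = 0.0038) and Akr1b7 (log2 1.71, limma adjusted p = 0.035) both passed. Of the 16 fits that left out 1 library this is the only 1 in which either did, and it removes the library with the lowest treated values of both. With array weights, which kept all 16 libraries and weighted them by their spread, both also passed in limma. Ren1 had a log2 of 4.31 (adjusted p = 0.0023) and Akr1b7 of 1.60 (adjusted p = 0.031). Such weights are lower for libraries far from their group. This fit is therefore not support separate from that of leaving out RAAS_blocked replicate 4. The weights of single libraries are not given here. Without RAAS_blocked replicate 4 the calls were 3 genes higher and 3 lower. The 3 others beside Rn18s were Mgat1, Ntf3 (log2 -1.02, adjusted p = 0.035) and Tiam1 (log2 -0.90, adjusted p = 0.045), the last pair named after their values were seen.

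**Figure D2:**
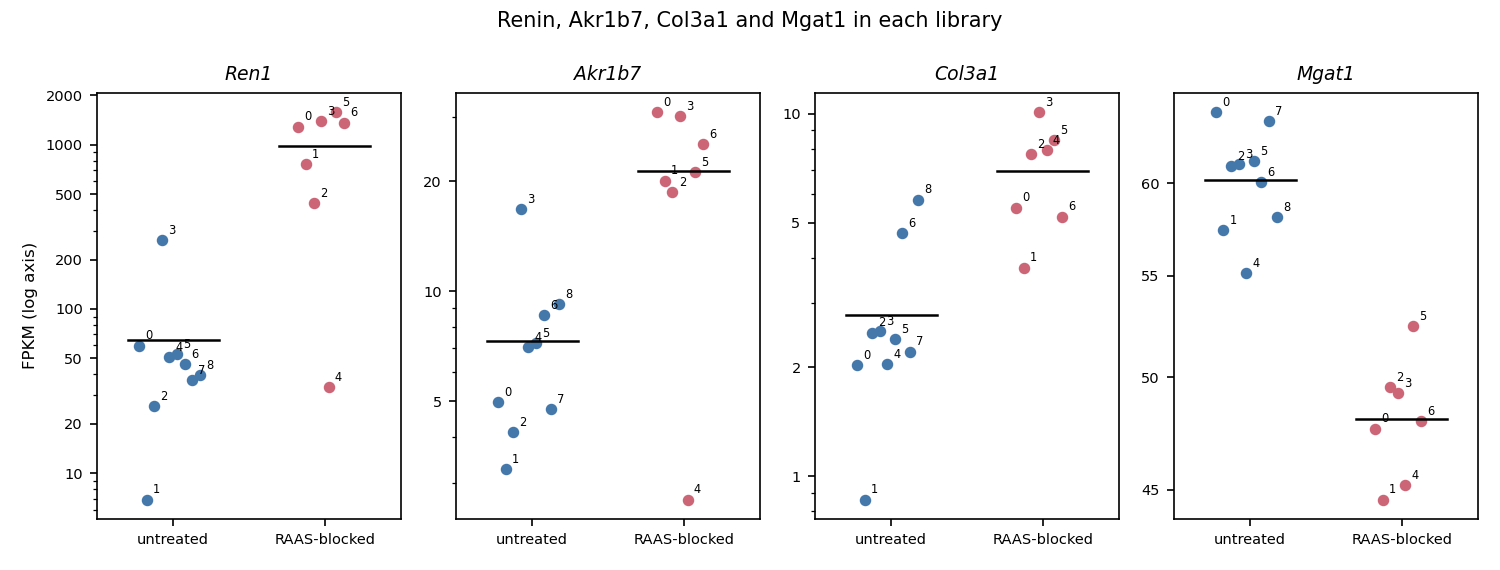
FPKM on log axes, with separate scales, of 4 genes in each library; points are libraries numbered by replicate and bars are group means. For Ren1 and Akr1b7 RAAS_blocked replicate 4 lies at 33.5 FPKM, among the untreated libraries, and at 2.70 FPKM, below all of them, while for Mgat1 all 7 treated libraries lie below the untreated ones.

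Other RAAS components showed no change that passed the test. Agtr1a, the angiotensin II receptor that losartan blocks, was at 86.7 ± 39.8 FPKM untreated and 114 ± 39.3 FPKM treated (log2 0.45 ± 0.28, limma adjusted p = 0.862). Ace, the target of lisinopril, was at 17.9 ± 5.01 and 15.6 ± 7.31 FPKM (log2 -0.23 ± 0.22, limma adjusted p = 0.919). Kng1, which encodes kininogen, was at 1.60 ± 0.951 and 0.980 ± 0.626 FPKM. Of the 23 tested RAAS components, 0 passed over all genes tested and 1, Ren1, when adjusted over the list alone, and the list as a whole did not stand apart from other genes (camera adjusted p = 0.772, up, with a mean log2 fold change of 0.19 and a median of -0.06).

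Genes of triacylglycerol synthesis and lipid droplets showed no group difference that passed the test. Of 20 tested members, 13 had lower and 7 higher means after RAAS blockade, and 0 passed over all genes tested or when adjusted over the list alone. Dgat1, which catalyses the last step of triacylglycerol synthesis, was at 13.3 ± 1.56 FPKM untreated and 14.2 ± 2.31 FPKM treated (log2 0.08 ± 0.09), and its counterpart Dgat2 was at 11.3 ± 7.34 and 8.43 ± 2.76 FPKM (log2 -0.25 ± 0.29). Gpam, the mitochondrial glycerol-3-phosphate acyltransferase, had the lowest p in the list, at 10.5 ± 3.14 and 7.78 ± 0.999 FPKM (log2 -0.36 ± 0.15, limma adjusted p = 0.755). Dgat2 and Gpam were highest in untreated replicates 1 (27.3 and 15.9 FPKM) and 4 (19.0 and 14.2 FPKM). These libraries also had the highest convoluted proximal tubule levels (4.96 and 4.88). The medians were 8.46 FPKM untreated and 8.51 FPKM treated for Dgat2, and 9.16 and 7.61 FPKM for Gpam. The lipin genes Lpin3 (log2 -0.20 ± 0.13) and Lpin1 (log2 -0.12 ± 0.10) and the lipid droplet coat genes Plin3 (log2 -0.11 ± 0.09) and Plin2 (log2 0.20 ± 0.27) had differences within 2 SE of 0. The list's camera adjusted p was 0.607.

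Among 12 genes of triacylglycerol hydrolysis, Angptl4, an inhibitor of lipoprotein lipase, was at 24.2 ± 14.2 FPKM untreated and 35.2 ± 5.90 FPKM treated (log2 0.72 ± 0.33, limma adjusted p = 0.801). Lpl itself was at 91.1 ± 44.4 and 69.3 ± 22.4 FPKM, and Gpihbp1, which anchors it to the endothelium, at 365 ± 99.6 and 306 ± 55.6 FPKM. Lmf1, a factor for lipase maturation, was at 13.7 ± 2.27 and 12.4 ± 1.59 FPKM. No member passed over all genes or when adjusted over the list alone (0 of 12 each), and the camera adjusted p was 0.607.

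Fatty acid synthesis and desaturation genes had lower means in 18 of 23 tested members. Scd2, a stearoyl-CoA desaturase, was at 82.3 ± 30.3 FPKM untreated and 60.9 ± 7.01 FPKM treated (log2 -0.36 ± 0.19, limma adjusted p = 0.824), and Scd1 was at 10.7 ± 3.50 and 8.05 ± 2.78 FPKM (log2 -0.37 ± 0.22, limma adjusted p = 0.856). Both desaturases were known from the study before the data were examined, so their direction is not independent evidence. Thrsp (log2 -0.46 ± 0.24) and Srebf1, the transcription factor of lipogenesis (log2 -0.16 ± 0.10), also had lower means. None of the 23 passed over all genes tested, 0 passed when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0959).

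The remaining lipid lists were likewise without members past the threshold. For fatty acid uptake and activation (17 genes, camera adjusted p = 0.805) Cd36, a fatty acid translocase, was at 15.5 ± 10.4 FPKM untreated and 19.7 ± 8.84 FPKM treated, and Fabp5 at 24.1 ± 4.78 and 19.6 ± 4.81 FPKM. Slc27a3 was at 24.9 ± 5.13 and 21.5 ± 5.81 FPKM and Acsl5 at 49.2 ± 4.16 and 54.5 ± 11.3 FPKM. In fatty acid oxidation (35 genes, camera adjusted p = 0.633) Acads, a short-chain acyl-CoA dehydrogenase gene, was at 32.7 ± 7.97 and 28.6 ± 7.18 FPKM (log2 -0.19 ± 0.16) and Crot, a peroxisomal carnitine acyltransferase gene, at 21.2 ± 3.12 and 24.2 ± 4.28 FPKM (log2 0.18 ± 0.11). In cholesterol synthesis (23 genes, camera adjusted p = 0.393) Idi1 was at 9.93 ± 2.32 and 12.3 ± 2.31 FPKM. Sc4mol (log2 0.25 ± 0.12) and Cyp51 (log2 0.24 ± 0.12) leaned the same way. The cholesterol list as a whole did not lean, with 12 higher and 11 lower means and a median log2 fold change of 0.007. In these 3 lists 0 members passed over all genes and 0 when adjusted over the list alone. Lcat, which esterifies cholesterol in lipoproteins, was at 0.867 ± 0.404 FPKM untreated and 1.65 ± 0.445 FPKM treated (log2 0.52 ± 0.14). It was the 1 member of 18 in the lipoprotein list to pass when adjusted over the list alone. None, 0 of 18, passed over all genes, and the list's camera adjusted p was 0.944.

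**Figure D3:**
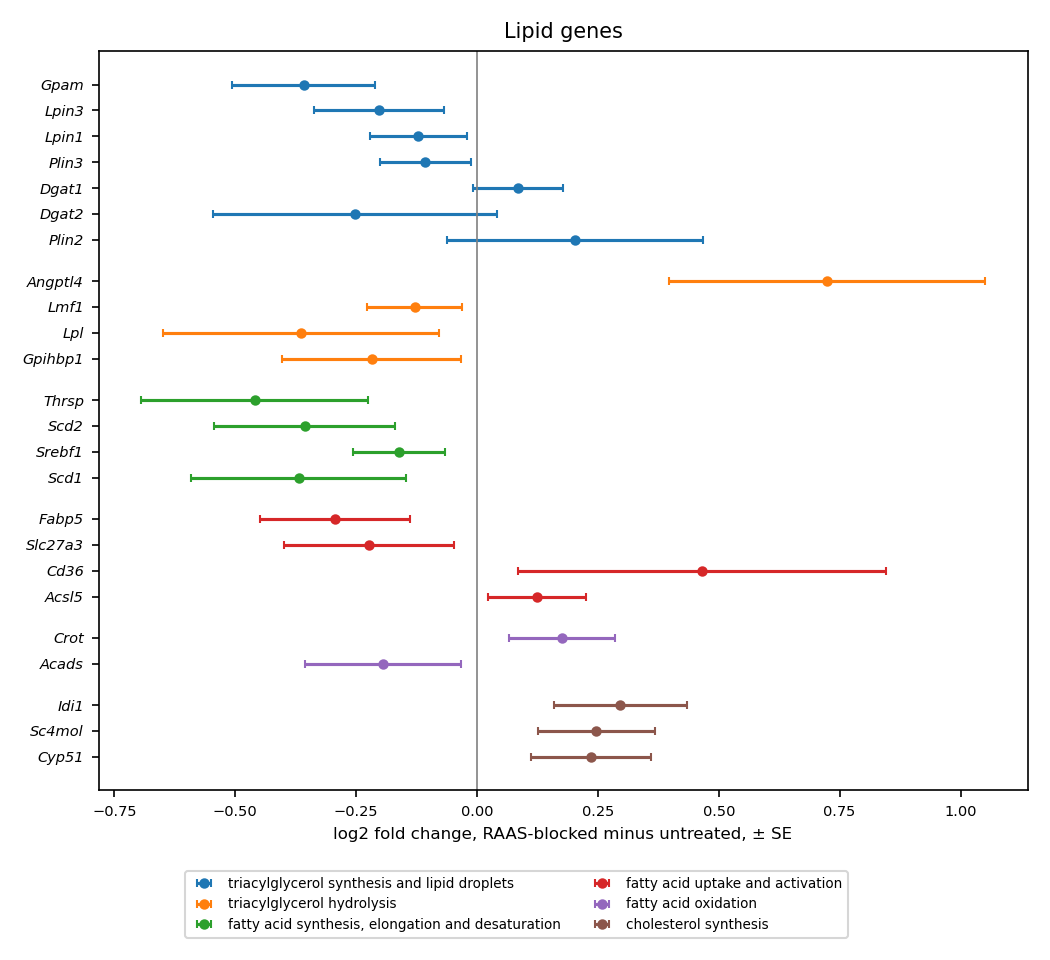
Log2 fold changes (RAAS-blocked minus untreated, on the log2(FPKM + 1) scale) of the named lipid genes, coloured by list; points are limma estimates from 9 untreated and 7 treated libraries and bars are ± 1 SE. None of the genes passed an adjusted p of 0.05, and Angptl4 (0.72) lies farthest above 0.

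No difference between the groups in how far lipid genes varied together passed the test. Over the 20 genes of triacylglycerol synthesis and lipid droplets, the mean pairwise Pearson correlation across libraries was 0.26 in untreated and 0.14 in RAAS-blocked mice, a difference of -0.12 (exact permutation p = 0.217, adjusted p = 0.921 over 6 lists). Fatty acid oxidation genes had the highest values, 0.67 and 0.50, and a difference of -0.17 (exact permutation p = 0.614, adjusted p = 0.921). Cholesterol synthesis had 0.49 and 0.39 and fatty acid uptake 0.16 and 0.17. Triacylglycerol hydrolysis (0.039 and -0.011) and fatty acid synthesis (0.060 and 0.057) had values near 0 in both groups. None of these differences passed the threshold. These correlations are across libraries and also carry the differences in tubule content.

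Clock genes had lower means after RAAS blockade in 14 of 17 tested. Over all genes tested 0 passed and 6 when adjusted over the list alone, all 6 lower. Bhlhe41, a repressor in the clock's feedback loop, was at 13.9 ± 5.35 FPKM untreated and 6.75 ± 2.24 FPKM treated (log2 -0.92 ± 0.23), and Gm129, the older symbol of Ciart, at 9.24 ± 2.94 and 4.41 ± 2.32 FPKM (log2 -0.98 ± 0.26). Dbp, an output transcription factor, was at 59.6 ± 18.6 and 31.6 ± 12.1 FPKM (log2 -0.89 ± 0.24), and Cry2 at 20.0 ± 3.97 and 14.4 ± 2.31 FPKM (log2 -0.44 ± 0.12). The list passed camera with its preset correlation (adjusted p = 0.00036, down), and its adjusted p = 0.438 with an estimated correlation. Clock time at collection was not given in the sources used here.

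**Figure D4:**
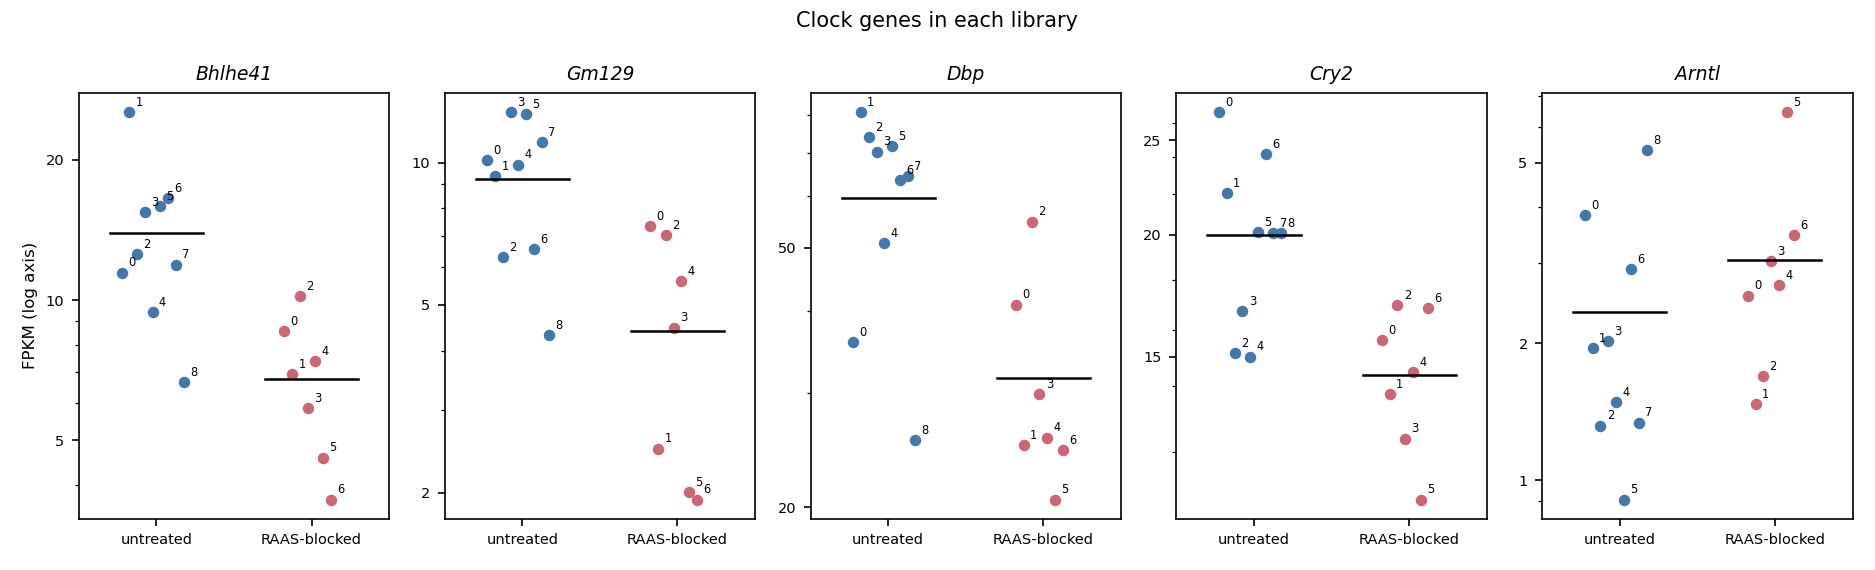
FPKM on log axes, with separate scales, of 5 clock genes in each library; points are libraries numbered by replicate and bars are group means. Bhlhe41, Gm129, Dbp and Cry2 have lower means in the RAAS-blocked group, while Arntl, which peaks when Dbp is low, has means of 2.35 and 3.05 FPKM.

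Most matrix, fibroblast and vessel wall genes had higher means after RAAS blockade. Col3a1, a fibrillar collagen gene, was at 2.78 ± 1.5 FPKM untreated and 6.96 ± 2.2 FPKM treated (log2 1.12 ± 0.24, limma adjusted p = 0.222). Col6a3 was at 3.59 ± 2.07 and 7.36 ± 3.14 FPKM, and Dcn (decorin) at 5.68 ± 3.29 and 8.97 ± 2.90 FPKM. Col15a1, a basement membrane collagen gene, went the other way, at 9.01 ± 3.20 and 5.72 ± 3.12 FPKM. Of 41 matrix genes 31 had higher means. The mean log2 level of the matrix list was lowest in untreated replicates 1 (3.85) and 4 (4.08). In untreated replicates 8, 0 and 3 it was 5.08, 5.02 and 4.99, above every treated library (4.71 to 4.96). Untreated replicates 1 and 4 also had the lowest fibroblast and mesangial levels and the highest convoluted proximal tubule levels (4.96 and 4.88). In the matrix list 0 passed over all genes and 1, Col3a1, when adjusted over the list alone (camera adjusted p = 0.00070; adjusted p = 0.811 with an estimated correlation). Fibroblast markers, of which 5 of 8 had higher and 3 lower means, share Col3a1, Dcn, Col1a1 and Col1a2 with that list, so the calls are not independent. The last pair was at 2.34 ± 1.62 and 4.31 ± 2.0 FPKM (Col1a1) and at 21.2 ± 11.0 and 29.7 ± 14.3 FPKM (Col1a2). The fibroblast list had 0 of 8 past over all genes and 1 when adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.679 with an estimated correlation). Smooth muscle and pericyte markers had higher means in 11 of 13, led by Rgs5 (67.1 ± 14.6 and 93.9 ± 21.3 FPKM) and Lmod1 (3.74 ± 1.37 and 5.41 ± 1.0 FPKM). Next came Acta2 (150 ± 62.5 and 223 ± 40.4 FPKM) and Tagln (44.4 ± 18.2 and 61.7 ± 13.9 FPKM). Of the 13 there were 0 past over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.00070; adjusted p = 0.811 with an estimated correlation). The lowest smooth muscle level of all belonged to untreated replicate 1, where Acta2 was at 38.3 FPKM. Mesangial and juxtaglomerular markers passed camera (adjusted p = 0.021; adjusted p = 0.811 with an estimated correlation) with 0 of 11 past over all genes and 2, Ren1 and Akr1b7, when adjusted over the list alone.

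Endothelial markers had lower means after RAAS blockade in 16 of 19 genes. Kdr, the main receptor for vascular endothelial growth factor A, was at 381 ± 97.6 FPKM untreated and 286 ± 108 FPKM treated, and Emcn (endomucin) at 704 ± 171 and 550 ± 130 FPKM. Ehd3 was at 503 ± 127 and 375 ± 134 FPKM and Tie1 at 140 ± 38.7 and 110 ± 17.6 FPKM. No member passed over all genes or when adjusted over the list alone (0 of 19 each; camera adjusted p = 0.0046; adjusted p = 0.880 with an estimated correlation). Erythrocyte genes had lower means in 6 of 6, with Hba-a1 at 71.9 ± 52.6 and 36.3 ± 47.4 FPKM and Hba-a2 at 45.7 ± 35.0 and 21.7 ± 26.9 FPKM. Hbb-b1 was at 27.5 ± 24.0 and 16.7 ± 27.4 FPKM and Alas2 at 2.81 ± 2.16 and 1.87 ± 2.82 FPKM. Of the 6, 0 passed over all genes or over the list alone (camera adjusted p = 0.011; adjusted p = 0.761 with an estimated correlation). The alpha globin copies are nearly identical, so the split of reads between them is uncertain. RAAS_blocked replicate 4 again departed from its group, with Hba-a1 at 139 FPKM and Hbb-b1 at 77.7 FPKM. Without it the treated means were 19.1 FPKM for Hba-a1, 12.0 for Hba-a2, 6.52 for Hbb-b1 and 0.822 for Alas2.

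Inflammatory and immune lists had higher means, the interferon list through a single mouse. Of 33 chemokine and inflammation genes 28 had higher means, among them Cxcl16 (28.5 ± 13.3 and 40.1 ± 9.74 FPKM) and Tlr4 (15.9 ± 6.47 and 20.5 ± 4.81 FPKM). The endothelial adhesion gene Sele (30.0 ± 30.3 and 59.3 ± 59.7 FPKM) and Cxcl1 (8.21 ± 6.74 and 13.1 ± 9.15 FPKM) had wide spreads, and without RAAS_blocked replicate 0 the treated mean of Sele was 38.4 FPKM. The list had 0 past over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.00038; adjusted p = 0.811 with an estimated correlation). Interferon-induced genes had higher means in 26 of 27. Ifit2, though, was at 90.6 FPKM in RAAS_blocked replicate 6 and at most 15.2 FPKM in the other treated libraries, whose mean of 11.6 FPKM compares with 11.0 FPKM in the untreated ones. Cmpk2, Usp18 and Ddx58 were also highest there. The interferon list had 0 members past over all genes or over the list alone (camera adjusted p = 0.00070; adjusted p = 0.899 with an estimated correlation). Without RAAS_blocked replicate 6 its direction turned and its adjusted p was 0.95. Macrophage and dendritic markers had higher means in 25 of 26, with Itgam at 6.36 ± 4.35 and 10.3 ± 7.47 FPKM and Ms4a6c at 9.91 ± 12.5 and 13.7 ± 7.12 FPKM. Ccr2 was at 5.32 ± 2.56 and 7.32 ± 3.84 FPKM and Lyz1 at 21.6 ± 16.5 and 29.6 ± 15.2 FPKM. The highest level of the list in all 16 libraries was that of untreated replicate 3 (mean log2 level 6.16, against at most 5.12 in a treated library). Without untreated replicate 3 the untreated mean of Ms4a6c was 5.83 FPKM. None of them passed over all genes or over the list alone (camera adjusted p = 0.0039; adjusted p = 0.899 with an estimated correlation).

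Tubular injury genes had higher means in 18 of 25. Cp (ceruloplasmin) was at 35.5 ± 18.6 FPKM untreated and 68.6 ± 17 FPKM treated (log2 1.04 ± 0.26, limma adjusted p = 0.421) and Gdf15 at 5.76 ± 2.89 and 15.9 ± 13.3 FPKM. Havcr1, which encodes kidney injury molecule, was at 2.86 ± 2.15 and 1.27 ± 2.19 FPKM. In RAAS_blocked replicate 4 Havcr1 was at 6.20 FPKM, and it did not exceed 0.944 FPKM in the other treated libraries, whose mean was 0.447 FPKM. Tmsb10 was at 202 ± 59.1 and 263 ± 90.9 FPKM. Of 25 genes 0 passed over all genes and 1, Cp, when adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.811 with an estimated correlation). Oxidative phosphorylation genes had lower means in 40 of 42 with small differences, such as Ndufa8 (log2 -0.21 ± 0.13), Ndufb3 (log2 -0.15 ± 0.10), Sdhb (log2 -0.26 ± 0.20) and Sdhc (log2 -0.17 ± 0.13). Of the 42, 0 passed over all genes or over the list alone (camera adjusted p = 0.035; adjusted p = 0.937 with an estimated correlation). The estimate changed with the nephron segment held constant, and without a covariate it was within 1 SE of 0. The list's mean log2 fold change was -0.10 ± 0.17 without a covariate. It was -0.073 ± 0.13 with the convoluted proximal tubule level as one, which ended the call (camera adjusted p = 0.096). With that of the thick ascending limb it was -0.035 ± 0.066. With the distal convoluted and connecting tubule level it was 0.0023 ± 0.078, on the other side of 0. The straight proximal tubule and intercalated levels also made it smaller. It grew to -0.14 ± 0.12 with the principal cell level and to -0.18 ± 0.13 with the thin limb and inner medulla level. These covariates were chosen after the data were seen.

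In all, 8 lists were higher and 4 lower with the preset correlation, and with an estimated correlation, with exact permutation of list scores and with fry 0 of 40 passed. The lowest adjusted p of those 3 tests were 0.438, 0.178 and 0.127, each for the clock genes.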

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

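The test of where RAAS_blocked replicate 4 lies among the groups was fixed before its result was seen, and the tests on its depth and on vessel wall markers after. Single libraries far from the rest of their group were looked for in 274 sets of values, those of 97 genes and 40 lists in each group, on the log2(FPKM + 1) scale. The rule, a gap to the nearest library that is large against the group's range, singled out 31, and 1 in 20 of the sets is 13.7. The sets overlap, since lists stand beside their own members, so 1 deviation can count several times. The 31 therefore do not show an excess over chance. RAAS_blocked replicate 6 held 10 of them, RAAS_blocked replicate 4 held 8, and untreated replicates 1 and 3 held 5 each.

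RAAS_blocked replicate 4 was the lowest of its group for Ren1 (33.5 FPKM, next 443), Akr1b7 (2.70 FPKM, next 18.6) and Angptl4 (23.1 FPKM, next 33.0). It was the highest for Havcr1 (6.20 FPKM, next 0.944), Alas2 (8.15 FPKM), Lepr (1.55 FPKM, next 0.480), Uty (8.20 FPKM) and the sex-linked list (mean log2 level 4.06). The library showed signs of low depth, with 16919 symbols above 0, the fewest of the 16. In FPKM low depth would scatter genes of a similar level without moving their median, so a test on the median, which was planned first, was dropped. Low depth is argued against as the source of the low Ren1, since of 746 genes at 100 to 2000 FPKM in the other treated libraries the 5th percentile of the log2 difference was -1.05 and the 95th 0.48, against -4.93 for Ren1, and 2 lay as far below. A general loss of smooth muscle cells and pericytes as large as the fall in Ren1 is also argued against. The 13 smooth muscle and pericyte markers were all lower, but by a median of only -0.45, from -0.88 to -0.04. These markers also cover pericytes and are not specific to the arteriolar wall, where renin is made, or to renin cells. A loss of arteriolar wall or of renin cells alone is therefore not excluded. Akr1b7, made by renin cells, differed by -2.75. A sample from an untreated mouse of the series stays open: of 100 genes chosen without this library, it lay nearer to the RAAS-blocked mean at 44, but RAAS_blocked replicate 6 did so at 49 and untreated replicate 3, which has the highest untreated Ren1 (263 FPKM), at 70, so the test could not separate single libraries. Its Rn18s, at 9925 FPKM, was the highest of its group (next 4246 FPKM). Its Mgat1 and Rn18s both lay on the side of its labelled group. Since the runs of library identifiers coincided with treatment, this can reflect the run and does not show that the mouse was treated. Drug intake of single mice is not given in the sources used here, and no biological explanation was tested.

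RAAS_blocked replicate 6 was the highest of its group for the interferon list (mean log2 level 6.94, next 4.42) and for Ifit2 (90.6 FPKM), Cmpk2 (64.7 FPKM), Usp18 (34.7 FPKM), Ddx58 (23.1 FPKM), Cxcl16 (60.8 FPKM) and Lcat (2.57 FPKM). It was also highest for the unfolded protein response list (5.69). It was the lowest for Lpl (25.6 FPKM, next 61.3) and for the white adipocyte list (4.56, next 5.36), of which Lpl is a member.

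Untreated replicate 1 was the lowest of its group for the smooth muscle and pericyte list (mean log2 level 3.67, next 4.59) and its members Rgs5 (36.1 FPKM), Lmod1 (1.15 FPKM), Acta2 (38.3 FPKM) and Tagln (11.3 FPKM). Untreated replicate 3 was the highest for the macrophage and dendritic list (6.16, next 4.37), the B and plasma cell list (4.16), Ms4a6c (42.5 FPKM, next 10.1), Cxcl16 (62.2 FPKM) and Dcn (13.9 FPKM). Single values elsewhere were Sc4mol at 26.5 FPKM in untreated replicate 6, Uty at 5.44 FPKM in untreated replicate 2 and Cyp51 at 8.21 FPKM in RAAS_blocked replicate 3.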

How the results depend on the processing

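Alternatives with the tubule covariate, with several libraries left out together or without Rn18s were chosen after seeing the data. Rn18s passed in every limma fit that included it; the rank test could hardly call single genes, since 47 would have to reach its lowest possible p of 0.00017. With Rn18s left out of the genes tested there were 0 higher and 0 lower, against 1 and 1, so Mgat1 lost its call (adjusted p = 0.088, against 0.044). Genes higher numbered 2 with no filter on low values, 5 with array weights and 0 in the exact Wilcoxon test. Genes lower numbered 6 with array weights and 0 with upper-quartile scaling, quantile normalization, eBayes without trend or robust, the exact Wilcoxon test and the tubule covariate. With the tubule covariate and without RAAS_blocked 4 there were 3 higher and 3 lower, without RAAS_blocked 4 and 6 together 2 and 0, and without untreated 3 as well 5 and 3. Leaving out 1 library at a time gave 1 to 3 genes higher and 0 to 3 lower. Without RAAS_blocked replicate 4 both were 3, without untreated replicate 8 the lower count was 3, and without any of untreated replicates 0, 1, 2, 3, 5, 6 and 7 or RAAS_blocked replicates 0, 1, 2, 3 and 6 it was 0.

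Lists higher numbered 4 to 10 and lists lower 2 to 7 over the fits that left out 1 library. Without untreated replicate 1 there were 4 higher, without untreated replicate 0 there were 7 lower, and without RAAS_blocked replicate 2 or 6 there were 2 lower. An estimated correlation, exact permutation and fry gave 0 and 0, and leaving out RAAS_blocked 4 and 6 together gave 5 higher. The interferon list turned to lower without RAAS_blocked replicate 6 (adjusted p = 0.95; without each other library the lowest was 6.3e-06) and without RAAS_blocked 4 and 6 (adjusted p = 0.880), and oxidative phosphorylation turned to higher in the latter (adjusted p = 0.464). In the fits that left out 1 library, the clock, smooth muscle, matrix and chemokine lists passed in 16 of 16. The endothelial list lost its call without RAAS_blocked replicate 6 (adjusted p = 0.102) and the erythrocyte list without RAAS_blocked replicate 2 (0.0512) or 6 (0.0594). Tubular injury lost it without untreated replicate 1 (0.174) or 5 (0.0587) or RAAS_blocked replicate 6 (0.278), and macrophages without untreated replicate 1 (0.0510) or RAAS_blocked replicate 2 (0.0502) or 3 (0.0802). Fibroblast markers lost it without untreated replicate 1 (0.0745) or 4 (0.0811) or RAAS_blocked replicate 2 (0.0502) or 4 (0.0532), mesangial markers without untreated replicate 1 (0.0650) or 4 (0.218) or RAAS_blocked replicate 1 (0.0815) or 2 (0.0750). Oxidative phosphorylation passed in 8 of 16 and lost its call without untreated replicate 1 (0.373), 2 (0.145), 4 (0.836) or 6 (0.134) or RAAS_blocked replicate 0 (0.170), 2 (0.405), 4 (0.842) or 6 (0.278). The triacylglycerol lists passed in 0 of 28 settings, fatty acid synthesis in 4 (lowest adjusted p = 0.035) and cholesterol synthesis in 2 (0.036), and 0 lipid lists differed in coordination in any setting. The scalings moved the median of all genes by less than 0.1. With the replicate block over 14 libraries 1 gene was higher and 0 lower, and 10 lists were higher and 9 lower. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.28 to 0.43, with 4 of 7 pairs over 0.1, and 1 of 7 libraries correlated best with its own number. Of 4191 single values compared with the setting of the report, 113 changed sign while past the threshold in neither. Where a count moved, the cause was not tested. Depth limits the genes near 1 FPKM most.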

Other observations

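The tests on Rn18s, on the lowest p without it, on nephron segments and on Arntl, Npas2 and Clock were chosen after the values were seen. So were the following genes, which stood out in single libraries and were not tested as a set. In RAAS_blocked replicate 6 Gbp2 was at 1466 FPKM (at most 59.7 FPKM in any other library), Irf1 at 605 FPKM (at most 75.5), Cxcl9 at 157 FPKM (at most 1.82) and Gbp5 at 125 FPKM (at most 6.37). In untreated replicate 3 Cd5l was at 144 FPKM (at most 17.3 in any other library), Spic at 24.7 FPKM (at most 5.06) and Marco at 22.1 FPKM (at most 2.97).

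Lists that have not yet been described did not pass camera in the main fit. Neutrophil markers (adjusted p = 0.0600, Mmp8 at 1.25 ± 1.13 and 2.80 ± 2.64 FPKM) and skeletal muscle markers (adjusted p = 0.0600, Myoz1 at 7.82 ± 4.36 and 3.78 ± 0.599 FPKM) came closest. The unfolded protein response came next (adjusted p = 0.0675, Manf at 20.3 ± 1.6 and 24.0 ± 2.37 FPKM). Over 28 alternative settings neutrophil markers passed in 8, the unfolded protein response in 7, and skeletal muscle and podocyte markers in 6 each. The other lists of this paragraph passed in at most 4. Podocyte markers (adjusted p = 0.153, Dach1 at 33.4 ± 11.3 and 26.4 ± 5.53 FPKM), intercalated cell markers (adjusted p = 0.224, Kit at 7.53 ± 2.06 and 5.25 ± 1.04 FPKM) and distal convoluted and connecting tubule markers (adjusted p = 0.283, Trpm6 at 6.03 ± 3.28 and 4.41 ± 2.74 FPKM) had mostly lower means. Other nephron lists were further off: principal cell markers (adjusted p = 0.445, Aqp4), thick ascending limb (0.607, Umod), thin limb and inner medulla (0.612, Bst1), and convoluted (0.633, Gatm) and straight proximal tubule (0.633, Slc16a9). B and plasma cell markers (0.314, Xbp1), T and NK cell markers (0.818, Lck), sex-linked transcripts (0.314, Uty), cell cycle (0.607, Tyms), immediate early genes (0.564, Myc) and glucose metabolism (0.723, Gpi1) did not pass either. White adipocyte markers (0.633, Tusc5) and oxidative stress genes (0.840, Sod1) had means and medians of opposite sign, and brown adipocyte markers (0.633) had a negative mean and median while camera placed them higher. Kcnk3 of the brown adipocyte list was the only member of these lists to pass when adjusted over the list alone (1 of 3), at 0.933 ± 0.262 and 1.65 ± 0.509 FPKM, and 0 members passed over all genes tested.

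Of 100 splits of the 16 libraries into 9 and 7, the real one included, 1 gave at least as many genes past the threshold as the real one, and the highest of the others called 0. Chance is excluded for the count of 2 genes only through Rn18s, which is at 0 in the whole of 1 group. Without it the real split called 0 genes, as did the others, so the count shows nothing for the rest. The lowest p over the remaining genes, that of Mgat1 (6.6e-06, or 5.18 as -log10 p), was reached by 1 of the 100 splits, the real one, and the nearest of the others had 7.9e-06 (5.10). That share alone would exclude chance for Mgat1, but the margin is narrow, 100 of 11440 splits were used and the test was chosen after the value was seen. With an adjusted p of 0.088 without Rn18s, chance is left open for this gene, as is a batch that follows the group. Chance is not excluded for the gene lists: 57 of 100 splits gave at least the 12 lists that the real split gave with the preset correlation, and the highest of the others gave 23. Splits that call more lists than the real one would go with a structure of the libraries that moves whole lists together. In the 12 lists that passed, the estimated correlation between genes ran from 0.09 (fibroblast markers) to 0.91 (oxidative phosphorylation). The preset of 0.01 therefore understates how far these genes move together. The cause of that structure was not tested.

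The presence of Rn18s in one group only was weighed next. A change of 18S ribosomal RNA in the tissue is argued against, since 9 of 9 untreated libraries list it at exactly 0 and every cell holds this RNA. A difference in processing or library batch that follows the group may account for it, but 0 of the runs of library identifiers hold both groups, so batch and treatment cannot be told apart for this or any other gene.

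The lower clock genes were weighed against tissue content and time of collection. Different tubule content is argued against as the whole cause. The mean log2 fold change of the list was -0.30 ± 0.08 without a covariate, and with the level of each of 7 nephron segment lists as a covariate in turn it ran from -0.32 ± 0.07 (intercalated cells) to -0.27 ± 0.06 (thin limb and inner medulla). The levels themselves differed by -0.23 to 0.14 between the groups, with exact permutation p of 0.502 or more. The convoluted proximal tubule, the segment tried first, gave -0.30 ± 0.08. A shift in the time of collection stays open: genes that peak when Dbp is low would then be higher, and the score of Arntl, Npas2 and Clock had a difference of 0.36 in that direction with an exact permutation p of 0.406, two-sided. Arntl and Dbp did vary against each other among mice of the same group, with r = -0.72 over 16 libraries centred within groups (permutation p = 0.0014, adjusted p = 0.0043 over 3 relations), rho = -0.64 (permutation p = 0.0090, adjusted p = 0.027) and r = -0.56 without the 2 libraries farthest from the median. An effect of RAAS blockade on the clock was not tested apart from time of collection.

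Within the untreated group alone the relation of Dbp and Arntl rested on 2 libraries, with r = -0.81 (permutation p = 0.0099, adjusted p = 0.015, n = 9) and rho = -0.68 (permutation p = 0.051, adjusted p = 0.076), and r = -0.032 without the farthest 2. In the RAAS-blocked group r was -0.58 (permutation p = 0.179, adjusted p = 0.179, n = 7) and rho was -0.61 (permutation p = 0.167, adjusted p = 0.167), and r was -0.58 without the farthest 2.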
